A study of Homo sapiens with 12 samples.

How the data were processed

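The series holds 12 RNA-seq libraries of primary human endometrial stromal cells in 4 groups of 3, made of nontargeting or PLZF siRNA for 48 h followed by 0 or 3 days of EPC. Per the labels' protocols, 250 ng of total RNA per sample went into an mRNA library kit that does not mark strand, with 15 PCR cycles, and both ends of the fragments were sequenced to 100 bases. The deposited values are raw read counts per gene symbol, made by the authors. The submitters' processing notes name STAR, Picard, HTSeq and the genome builds hg19 and GRCh37, with no versions, roles or annotation given in the sources used here. Reads of a gene and an overlapping antisense gene cannot be told apart in such libraries, and reads shared by near-identical genes may have been split or dropped. The table holds 25369 symbols, of which 20416 had a count, and 0 symbols lacked a name. None of the 13 mitochondrially encoded genes of the list fixed for them is in the table, so that list has no result.

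Groups were taken from the labels. The sample titles carry 1 of 3 codes that the 4 groups share, written here as replicates 1 to 3, and the series names 3 volunteers. To check whether the numbers pair the libraries, deviations of log2 CPM from the group means were correlated. Libraries of the same number correlated at 0.548 to 0.869, and libraries of different number and group at -0.528 to -0.157, so the numbers pair the libraries. The main fit, fixed beforehand, leaves this pairing out and recovered fewer simulated changes than the fit with the replicate number as a block. A gene that did not pass in the main fit may therefore still have changed. Counts with the block are given for each comparison as a whole and for some genes and lists, not for every list that it changes. Library pairs within a group differed by far more than sampling noise (chi-square per degree of freedom 72.3 to 153), so no library was counted as a copy of another. Without the block, the p-values count differences between replicates that the compared groups share as part of the spread. With the block, they measure the spread left between these 3 sets of cultures after the replicate number is taken out. Totals ran from 39753312 to 49752711 counts, and intervals and floors from counts cover counting error only, since PCR copies were not marked by molecular identifiers.

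Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr with a minimum count of 10) in R 4.3.3, on all 12 libraries with 4 group means and no block, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 14834 genes, and the genes left out held 0.0195% of all counts. The design was fixed before the data were examined. The 5 contrasts were EPC day 3 against day 0 within each siRNA, PLZF against nontargeting siRNA within each day, and their interaction. SE values are those of the fitted log2 fold change. CPM values use TMM-scaled library sizes and are given as mean ± SD where a spread is shown. The floor was 3 counts. Genes of the Y chromosome and XIST were left out of all tables of single genes. The common biological coefficient of variation was 0.313 without and 0.147 with the block.

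The genes named in each comparison followed a rule fixed before the data were examined. It takes ZBTB16, the 10 highest and 10 lowest log2 fold changes past the threshold among genes with an average log2 CPM of at least 1 and the same direction in all 3 pairs (filled up from the fit with the block where fewer passed), up to 4 members with the smallest p of each list discussed, and PRL, IGFBP1, FOXO1, HAND2, BMP2, WNT4, PGR and EGR1. Further list members were named after their values were seen where 5 or fewer of a list passed, as were THBS1, FOSB and PCSK9. There were 25 gene lists fixed in the same way, for decidual markers, hormone and cAMP responses, cell cycle, metabolism, matrix, signalling and markers of epithelial, endothelial, leukocyte and perivascular cells, of which 24 had tested members. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the lists of a contrast, and again with a correlation estimated per list. Members were also adjusted over the list alone.

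The alternatives planned beforehand were RLE scaling, DESeq2 1.42.0, no low-count filter, only the 6 libraries compared, the replicate block, the block with RLE scaling, and leaving out each library or replicate number in turn. Overlaps of calls were compared with 20 simulations of unchanged groups and with independent lists. The simulated genes varied independently of each other, so the simulated ranges hold no variation that genes share between cultures. The fits of EPC with nontargeting siRNA and of PLZF siRNA at each day were tested on simulated counts with 200 changed genes. EPC with PLZF siRNA and the interaction were not simulated, so the share of changes that their fits recover is not known. For PLZF siRNA at day 0 the fit without the block, run on 14721 genes, recovered 47% of genes changed 2-fold and 83% of those changed 4-fold, and the fit with the block 81% and 100%. For day 3, on 14699 genes, it recovered 59% and 86%, and with the block 89% and 99%. For EPC with nontargeting siRNA, on 14660 genes, the shares were 65% and 85%, and 93% and 98% with the block. False calls numbered 0 to 1 without and 11 to 18 with the block. The simulated counts held the same replicate differences at both days, while the real EPC response differed in size between replicates. For PLZF siRNA at day 0 the block fit on the 6 libraries recovered 74% of 2-fold changes, against 81% on all 12. In the real counts it called 5703 genes, against 1335. The recovered shares may therefore not hold for the real fits. A search of 7-base words in 3′ untranslated regions used the GENCODE annotation of GRCh38 for its sequences only, since no coordinates of the build named by the submitters were used, with Python 3.11.15 and numpy 2.4.6. It covered 13398 of 14831 genes (90.3%), counted words of 7 bases in regions of at least 50 bases, tested words found in at least 30 genes and permuted genes for its p.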

Results

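RNA sequencing was performed on primary human endometrial stromal cells, the fibroblast-like cells of the uterine lining, isolated from 3 healthy volunteers. The cells were transfected for 48 h with a nontargeting siRNA or with an siRNA against PLZF, the zinc finger transcription factor encoded by ZBTB16. They were then treated with EPC, a mixture of estradiol, medroxyprogesterone acetate and cAMP that induces decidualization, the differentiation of these cells that prepares the lining for pregnancy. Cells were collected on day 0 or day 3 of EPC. The 4 groups held 3 libraries each, numbered 1 to 3 by a code that the groups share. Total counts were 41073079 to 47489093 per library for nontargeting siRNA at day 0, 44089473 to 49752711 for PLZF siRNA at day 0, 39753312 to 46550709 for nontargeting siRNA at day 3 and 40570188 to 41720818 for PLZF siRNA at day 3. At this depth 14834 of the 20416 genes with a count could be tested. On a principal component analysis, component 1 held 55.4% of the variance and separated the days, with the day 3 libraries of replicate 3 at 19.9 (nontargeting siRNA) and 34.6 (PLZF siRNA) and the other 4 day 3 libraries between 57.6 and 82.6.

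ZBTB16, the target of the siRNA, was close to absent before EPC. It had 2, 1 and 1 counts in the nontargeting siRNA libraries of replicates 1 to 3 at day 0, and 0, 0 and 3 counts in the libraries labelled PLZF siRNA at day 0. Every day 0 library lay at or under the floor of 3 counts, and no fold is given for that day. At day 3 it had 571, 841 and 266 counts with nontargeting siRNA and 326, 360 and 263 counts in the libraries labelled PLZF siRNA. The mean level at day 3 was 13.3 ± 6.55 CPM (SD, n = 3; CPM, counts scaled to library size) with nontargeting siRNA and 7.93 ± 1.39 CPM (SD, n = 3) with PLZF siRNA. The log2 fold change was -0.74 ± 0.49 (SE) with an adjusted p of 0.993 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and -0.63 ± 0.30 with an adjusted p of 0.330 when the replicate number was a block. ZBTB16 was lower in 2 of the 3 pairs, by log2 differences of -0.82 and -1.06, and 0.06 higher in the remaining pair. The difference in this transcript was therefore within the spread between replicates. At day 3 ZBTB16 was not lower in 1 library labelled PLZF siRNA, at 6.41 CPM against 6.13 CPM in its nontargeting pair. Every direction given for PLZF siRNA rests on the labels.

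**Figure D1:**
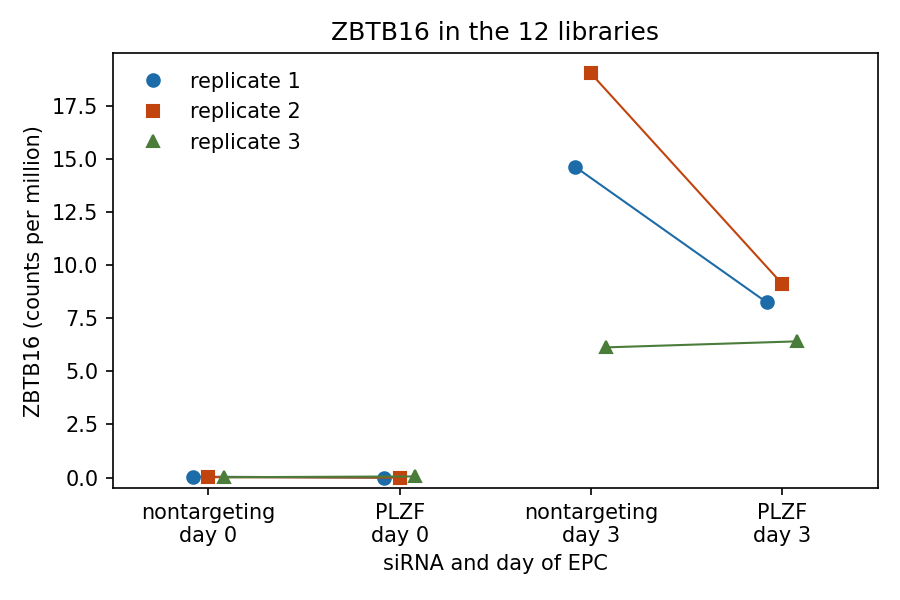
ZBTB16 level in CPM (y axis) in each of the 12 libraries, by siRNA and day of EPC (x axis). Points are single libraries and lines join libraries of the same replicate number within a day. All day 0 libraries lie near 0, the nontargeting day 3 libraries lie between 6.13 and 19.0, and the libraries labelled PLZF siRNA at day 3 lie between 6.41 and 9.13.

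The first comparison asked how stromal cells that had received nontargeting siRNA differed between day 0 and day 3 of EPC. No group was kept for 3 days without EPC. Effects of EPC, here and below, therefore cannot be told apart from those of 3 more days in culture and after transfection. IGFBP1, a secreted binding protein of insulin-like growth factors and a classical marker of decidual cells, rose from 0.293 to 29.5 CPM (log2 fold change 6.66 ± 0.62, SE, n = 3 per group), and PRL, which encodes prolactin, rose from 0.0501 to 4.36 ± 3.98 CPM (SD). IGF1, encoding insulin-like growth factor 1, reached 63.5 ± 77.9 CPM (SD) from 7 counts over the 3 day 0 libraries. CNR1, the cannabinoid receptor 1 gene, had 7246 counts at day 3 against 3 at day 0, a ratio of 2623 with a 95% counting interval of 897 to 12722. Most of its counts came from the day 3 library of replicate 2, without which the ratio was 873. SST, the somatostatin gene, had 2113 against 3, a ratio of 765 with an interval of 261 to 3712. The counting interval leaves out the spread between libraries, which for IGF1 exceeded its mean. ZBTB16 itself had 1678 counts against 4, a ratio of 456 with an interval of 178 to 1674.

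Of the 33 decidual markers in a list fixed before the data were examined, 26 rose and 1 fell over all genes tested, and 28 rose and 1 fell adjusted over the list alone. FOXO1, a transcription factor required for decidualization, rose by 2.82 ± 0.52 on the log2 scale, HAND2, a progesterone-dependent transcription factor, by 2.11 ± 0.41, and WNT4, a secreted WNT ligand, by 5.07 ± 0.63. PTGER4, a prostaglandin E2 receptor, was the member that fell (-1.21 ± 0.37). The list was higher than other genes in limma's camera test (adjusted p = 6.22e-11, and adjusted p = 0.0257 with an estimated correlation). PGR, the progesterone receptor gene, rose by 1.67 ± 0.49. BMP2, a morphogen of the TGF-beta family, had a log2 fold change of 1.09 ± 0.40 with an adjusted p of 0.0583. With the replicate block it was at 0.99 ± 0.19 with an adjusted p of 0.00220, both from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. EGR1, an immediate early transcription factor, was at -1.16 ± 0.64, not past the threshold without the block (adjusted p = 0.188) and past it with the block (-1.08 ± 0.38, adjusted p = 0.0416, edgeR quasi-likelihood, Benjamini-Hochberg).

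Other genes with strong increases were P2RY14, a receptor for UDP-glucose (20.6 ± 21.8 CPM, SD, at day 3 from 6 counts at day 0), LEFTY2, a secreted TGF-beta family member (6.28 ± 7.53 CPM from 5 counts), SERPINA3, a protease inhibitor (8.80 ± 7.93 CPM from 0.0875), DIRAS2, a small GTPase (log2 fold change 6.55 ± 0.78), and COL15A1, a collagen of basement membrane zones (6.53 ± 1.04). Among the strongest decreases were those of SERPINB7, a serpin (-5.88 ± 0.50), RGS4, a regulator of G protein signalling (-5.62 ± 0.41), ANKRD1, an ankyrin repeat protein (-5.40 ± 0.52), MALL (-4.98 ± 0.34), LYPD1 (-4.90 ± 0.41), ESAM, a cell adhesion molecule (-4.12 ± 1.14), KCNA3, a potassium channel (-4.03 ± 0.60), PDGFB, a platelet-derived growth factor chain (-3.99 ± 0.31), EDN1, the endothelin 1 gene (-3.90 ± 0.49), and CDH6, a cadherin (-3.84 ± 1.03).

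Cell cycle genes fell together. In the G1/S and DNA replication list 24 of 25 genes fell, and 25 adjusted over the list alone, among them the helicase subunit gene MCM2 (-1.87 ± 0.31) and the cyclin gene CCND1 (-2.03 ± 0.34). In the G2/M and mitosis list 20 of 28 genes fell, and 27 adjusted over the list alone, including CDC20, an activator of the anaphase-promoting complex (-2.99 ± 0.75), and FOXM1, a mitotic transcription factor (-2.66 ± 0.66). The camera adjusted p was 2.77e-10 for the first list and 1.98e-09 for the second, and adjusted p = 0.438 with an estimated correlation for both.

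Genes of cholesterol synthesis and uptake rose, 14 of 22 over all genes and 16 adjusted over the list alone. LDLR, the LDL receptor gene, rose by 1.70 ± 0.11 and HMGCR, the rate-limiting enzyme of the pathway, by 1.12 ± 0.10 (camera adjusted p = 5.85e-08, and adjusted p = 0.190 with an estimated correlation). Among 25 progestin and glucocorticoid responsive genes 17 rose, and 17 rose and 1 fell adjusted over the list alone, with TSC22D3, a glucocorticoid-induced leucine zipper gene, at 2.76 ± 0.28 (camera adjusted p = 2.47e-05, and adjusted p = 0.145 with an estimated correlation). Among 21 cAMP and CREB responsive genes 10 rose and 1 fell, and 11 and 1 adjusted over the list alone, with the phosphodiesterase gene PDE7B at 4.29 ± 0.52 and the AP-1 gene FOSB at -1.40 ± 0.41 (camera adjusted p = 0.00193, and adjusted p = 0.0648 with an estimated correlation). In the extracellular matrix and basement membrane list 17 of 34 genes rose and 1 fell, the same counts adjusted over the list alone, with FBLN1, encoding fibulin 1, at 2.18 ± 0.25 and the laminin gene LAMC1 at 0.93 ± 0.09. THBS1, encoding thrombospondin 1, fell by 1.45 (± 0.35) (camera adjusted p = 0.000122, and adjusted p = 0.478 with an estimated correlation). In the glycolysis list 8 of 22 genes fell, and 11 fell and 2 rose adjusted over the list alone, with the enolase gene ENO1 at -0.74 ± 0.11 and the pyruvate kinase gene PKM at -0.86 ± 0.19 (camera adjusted p = 0.0181, and adjusted p = 0.438 with an estimated correlation). Of 29 cytosolic ribosomal protein genes RPL10 (0.34 ± 0.08), RPS27 (0.32 ± 0.09), RPL5 (0.25 ± 0.08), RPLP0 (0.24 ± 0.08) and RPL13 (0.22 ± 0.08) rose over all genes. edgeR called 0 adjusted over the list alone, where the replicate block called 18 (camera adjusted p = 0.00822, and adjusted p = 0.684 with an estimated correlation). This list had a median log2 fold change of only 0.17.

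The remaining lists did not pass camera at an adjusted p of 0.05 without the block, although single members moved. Of 20 immediate early genes 7 fell and 3 rose, with 8 and 3 adjusted over the list alone. FOSL1, an AP-1 subunit, was at -2.74 ± 0.30 among those that fell, and KLF4 (3.12 ± 0.35), JUN (0.82 ± 0.20) and JUND (0.42 ± 0.08) rose. Of 23 matrix remodelling enzymes and inhibitors 10 rose and 2 fell, with the same counts adjusted over the list alone. TIMP3, a metalloproteinase inhibitor, rose by 3.11 ± 0.40, and the collagenase gene MMP1 (-2.93 ± 0.81) and the stromelysin gene MMP10 (-2.61 ± 0.63) fell. In the steroid receptor list PGR, NCOA1 (0.85 ± 0.14), PGRMC1 (0.72 ± 0.23) and PGRMC2 (1.20 ± 0.19) rose and the cochaperone gene FKBP4 fell (-0.77 ± 0.08), 4 and 1 of 14 also adjusted over the list alone. The camera adjusted p was 0.103 for immediate early genes, 0.0609 for matrix enzymes and 0.114 for steroid receptors. Each was 0.0471 with the replicate block, and adjusted p = 0.442, 0.540 and 0.319 with the block and an estimated correlation.

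Signalling and stress lists were mixed. Of 25 WNT signalling genes 8 rose and 3 fell, with 10 and 4 adjusted over the list alone, including AXIN2, a feedback inhibitor (2.58 ± 0.39), and the receptor gene FZD2 (-0.74 ± 0.07). TCF7 (-1.47 ± 0.26) and NOTUM (-1.65 ± 0.47) fell as well. Of 27 TGF-beta, BMP and activin genes 6 rose and 5 fell, with 7 and 5 adjusted over the list alone. NOG, which encodes the BMP antagonist noggin, fell by 2.65 (± 0.34), as did SMAD3 (1.38 ± 0.39), SMAD7 (0.86 ± 0.18), ID2 (1.31 ± 0.38) and GREM2 (2.19 ± 0.60). Of 24 HOX and mesenchymal transcription factor genes 7 rose, MEIS1 by 2.36 ± 0.26, and HOXA9 (-0.75 ± 0.16) and GATA2 (-0.84 ± 0.15) fell, with the same counts adjusted over the list alone. Of 21 unfolded protein response genes 6 rose, DNAJB9 by 1.29 ± 0.10, and SDF2L1 (-0.67 ± 0.22) and PPP1R15A (-0.59 ± 0.19) fell, with the same counts adjusted over the list alone. Among 20 cell cycle inhibitors and p53 targets CDKN1C, encoding the inhibitor p57, rose by 3.01 ± 0.53, with GADD45A (1.16 ± 0.23), TP53INP1 (0.99 ± 0.23) and SESN1 (0.62 ± 0.18), while BAX (-0.74 ± 0.22), FDXR (-0.66 ± 0.13) and RPS27L (-0.53 ± 0.14) fell, 5 and 3 adjusted over the list alone. Among 15 cytokine genes IL15 (2.01 ± 0.24), TNFAIP3 (2.45 ± 0.51) and NFKBIA (0.55 ± 0.12) rose, and IL6 (-2.79 ± 0.71) and CXCL8 (-1.21 ± 0.34) fell, the same 3 and 2 adjusted over the list alone. In the interferon list 1 of 22 genes fell, also adjusted over the list alone, IFIT2 at -1.93 ± 0.23. With the block 5 interferon genes rose and 5 fell, and 4 and 4 adjusted over the list alone. Of 23 actin and contractile genes 5 rose and 4 fell, with 6 and 4 adjusted over the list alone. ACTA2, smooth muscle actin, rose by 1.44 ± 0.31, with CNN1 (1.38 ± 0.45), TAGLN (0.50 ± 0.10), MYL9 (0.37 ± 0.09) and CALD1 (0.34 ± 0.11), and FLNC (-1.13 ± 0.26), ACTN4 (-0.84 ± 0.09), CNN2 (-0.56 ± 0.14) and ACTN1 (-0.43 ± 0.09) fell. The camera adjusted p was 0.279 for WNT, 0.849 for TGF-beta, 0.104 for HOX, 0.153 for unfolded protein response, 0.870 for p53, 0.555 for cytokine, 0.839 for interferon and 0.731 for actin lists.

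Markers of other cell types of the uterine lining were tested as well. Of 10 epithelial markers the keratin genes KRT18 (-3.38 ± 0.27), KRT7 (-2.88 ± 0.72), KRT19 (-2.02 ± 0.32) and KRT8 (-1.49 ± 0.22) fell and the mucin gene MUC1 rose (1.38 ± 0.40), the same 4 and 1 adjusted over the list alone. Of 9 endothelial markers ESAM, ROBO4 (-4.52 ± 0.62) and ENG (-0.38 ± 0.13) fell and EGFL7 rose (0.74 ± 0.23), with 4 and 1 adjusted over the list alone. Of 13 perivascular markers 5 rose, and 5 adjusted over the list alone, which were ACTA2, CNN1, MCAM (1.96 ± 0.40), PDGFRB (1.11 ± 0.37) and STEAP4, which had 0 counts at day 0. The leukocyte list had 1 of 7 genes higher, LCP1, an actin-bundling protein, at 2.55 ± 0.81, and edgeR called 0 adjusted over the list alone and 1 higher and 1 lower with the block. The camera adjusted p was 0.133 for epithelial, 0.0935 for endothelial, 0.104 for perivascular and 0.901 for leukocyte markers. For endothelial markers it was 0.0471 with the replicate block, and adjusted p = 0.339 with the block and an estimated correlation.

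In all, 2612 genes rose and 2572 fell between day 0 and day 3 with nontargeting siRNA at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1140 and 1008 of them by more than 2-fold. The replicate block called 4410 higher and 4149 lower genes. Without the nontargeting day 3 library of replicate 3 the counts were 2621 and 2728, and without all 4 libraries of a replicate number they were 1089 and 1042 (replicate 1), 1310 and 1250 (replicate 2) and 1704 and 1813 (replicate 3).

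**Figure D2:**
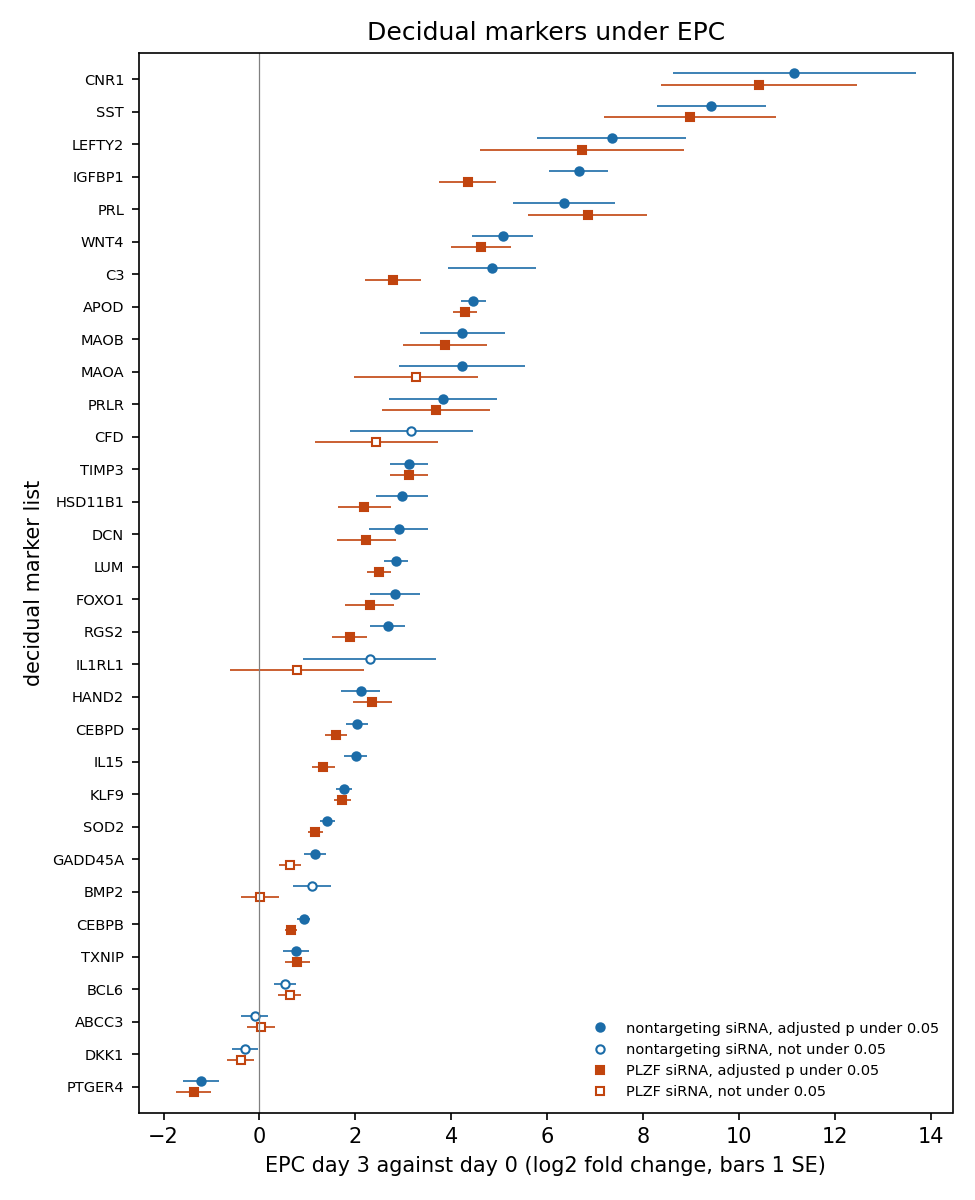
Log2 fold change of the decidual markers between day 3 and day 0 of EPC (x axis, bars 1 SE) for nontargeting siRNA (circles) and PLZF siRNA (squares), ordered by the value with nontargeting siRNA. Filled symbols have an adjusted p under 0.05, and SCARA5, with 0 counts in the day 0 groups, is left out. With nontargeting siRNA CNR1 is at the top at 11.14 and PTGER4 is at the bottom.

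The second comparison was PLZF against nontargeting siRNA at day 0, before EPC was given and while ZBTB16 was at the floor. SMC1A, a cohesin subunit, fell by 1.37 on the log2 scale (± 0.22, SE, n = 3 per group), from 278 to 107 CPM, SMARCD1, a subunit of SWI/SNF chromatin remodellers, fell by 1.08 (± 0.16), RRP1B and NOLC1, both nucleolar proteins, fell by 1.20 (± 0.17) and 0.99 (± 0.11), and MAPK3, the kinase ERK1, fell by 1.03 (± 0.12). HIST1H2BK, a histone H2B gene whose near-identical family members may share reads, had a log2 fold change of -1.41 ± 0.20 and is uncertain for that reason. HDHD1 (-1.23 ± 0.11), PM20D2 (-1.38 ± 0.23), TXNDC16 (-1.10 ± 0.14) and MTRR, methionine synthase reductase (-1.04 ± 0.18), also fell. Among the genes that rose were FOXO4, a forkhead transcription factor (0.84 ± 0.14), TRPM4, a cation channel (0.82 ± 0.09), JARID2, a subunit of Polycomb repressive complex 2 (0.80 ± 0.13), BCAS3 (0.60 ± 0.10), PSKH1 (0.57 ± 0.09), YPEL5 (0.56 ± 0.09), HECTD3, a ubiquitin ligase (0.53 ± 0.09), the noncoding RNA LINC00657 (0.51 ± 0.08), TMEM159 (0.50 ± 0.08) and ZER1 (0.47 ± 0.08).

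The decidual genes named above did not pass at day 0. PRL was at 0.0501 and 0.0271 CPM, IGFBP1 at 0.293 and 0.344 CPM, and FOXO1 at a log2 fold change of 0.22 ± 0.52. The genes of the G1/S list lay below other genes as a set, with a median log2 fold change of -0.93. In edgeR 0 of the 25 passed over all genes and 4 fell adjusted over the list alone, while the replicate block called 9 lower over all genes and 22 adjusted over the list alone. MCM2 had -1.10 ± 0.31 without the block (adjusted p = 0.190) and -1.12 ± 0.17 with it (adjusted p = 0.0103, edgeR quasi-likelihood, Benjamini-Hochberg). The camera adjusted p was 2.51e-10 for this list and 0.000106 for G2/M and mitosis, where edgeR called 0 of 28 genes over all genes or adjusted over the list alone, with and without the block, and adjusted p = 0.976 with an estimated correlation for both lists. With the replicate block camera also placed the extracellular matrix list (adjusted p = 0.00589) and the type I interferon list (adjusted p = 0.0108) above other genes, and adjusted p = 0.930 with an estimated correlation for both. In the interferon list 5 of 22 genes rose with the block, and 6 adjusted over the list alone. They were IFI44L (1.58 ± 0.33), OAS1 (0.98 ± 0.25), the double-stranded RNA sensors IFIH1 (0.79 ± 0.17) and DDX58 (0.51 ± 0.13), and the interferon regulatory factor gene IRF7 (0.66 ± 0.13). Without the block edgeR called 0 of the 22 and IFIH1 was at 0.85 ± 0.38. In the matrix list COL1A2 (0.36 ± 0.09) and NID1 (0.38 ± 0.10) rose with the block, and 4 adjusted over the list alone. The camera adjusted p without the block was 0.0720 for the matrix and 0.163 for the interferon list, and at least 0.232 for each list not named here.

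In all 11 genes were higher and 41 lower with PLZF siRNA at day 0 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1 and 9 of them by more than 2-fold, and all 52 were called in the same direction with the replicate block, which called 618 higher and 717 lower. DESeq2 called 219 and 363. Fitted on the 6 day 0 libraries alone, edgeR called 0 and 0 without the block and 3072 and 2631 with it. Leaving out any 1 of the 6 libraries, or any replicate number, brought the counts without the block to 0 to 2 higher and 0 to 11 lower, the highest without the PLZF siRNA library of replicate 1. With the block the counts were 0 to 337 and 0 to 541, with 0 and 0 in edgeR without each replicate number.

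The third comparison was PLZF against nontargeting siRNA at day 3 of EPC. ZBTB16 was not shown to be lower there, so differences in this contrast cannot be credited to loss of PLZF. DERL1, a membrane protein of endoplasmic reticulum-associated degradation, fell from 206 to 112 CPM (log2 fold change -0.88 ± 0.09, SE, n = 3 per group, adjusted p = 0.0261). NRBF2, a subunit of an autophagy lipid kinase complex, fell from 51.7 to 28.4 CPM (-0.86 ± 0.10, adjusted p = 0.0356). Each fell in 3 of 3 pairs, and the adjusted p are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Both were also lower at day 0, while ZBTB16 was at the floor. IGFBP1 was at 29.5 CPM with nontargeting and 7.00 CPM with PLZF siRNA and lower in all 3 pairs, with a log2 fold change of -2.07 ± 0.54 that did not pass over all genes (adjusted p = 0.390 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and 0.0867 with the block). PRL was at 4.36 and 3.46 CPM (-0.34 ± 0.77), FOXO1 at -0.30 ± 0.52, HAND2 at 0.05 ± 0.41, WNT4 at -0.05 ± 0.59, BMP2 at -0.52 ± 0.40, PGR at -0.01 ± 0.49 and EGR1 at -0.03 ± 0.64, none past the threshold.

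With the replicate block the named genes that fell at day 3 also included SST (log2 fold change -1.89 ± 0.23 with the block), MAP7, a microtubule-associated protein (-1.76 ± 0.17), ADAMTS4, a proteoglycan-cleaving protease (-1.61 ± 0.29), LINC00473, a noncoding RNA induced by cAMP (-1.33 ± 0.24), FRMD8 (-1.18 ± 0.18), RSPO3, an enhancer of WNT signalling (-1.14 ± 0.19), FABP3, a fatty acid binding protein (-1.12 ± 0.18), and SOCS3, a suppressor of cytokine signalling (-1.12 ± 0.18). Those that rose with the block were ADRA2A, an adrenergic receptor (1.70 ± 0.14), LINC00643 (1.63 ± 0.26), GNA14, a G protein subunit (1.42 ± 0.20), SYT15 (1.28 ± 0.25), RASL11A (1.26 ± 0.18), ASPN, a matrix proteoglycan (1.19 ± 0.17), KLHL35 (1.14 ± 0.16), INA, an intermediate filament protein (1.11 ± 0.11), PDE8B, a phosphodiesterase (1.04 ± 0.15), and FRY (1.03 ± 0.12). None of these 18 passed without the block, where the lowest adjusted p were 0.0543 for INA and 0.0648 for MAP7.

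**Figure D3:**
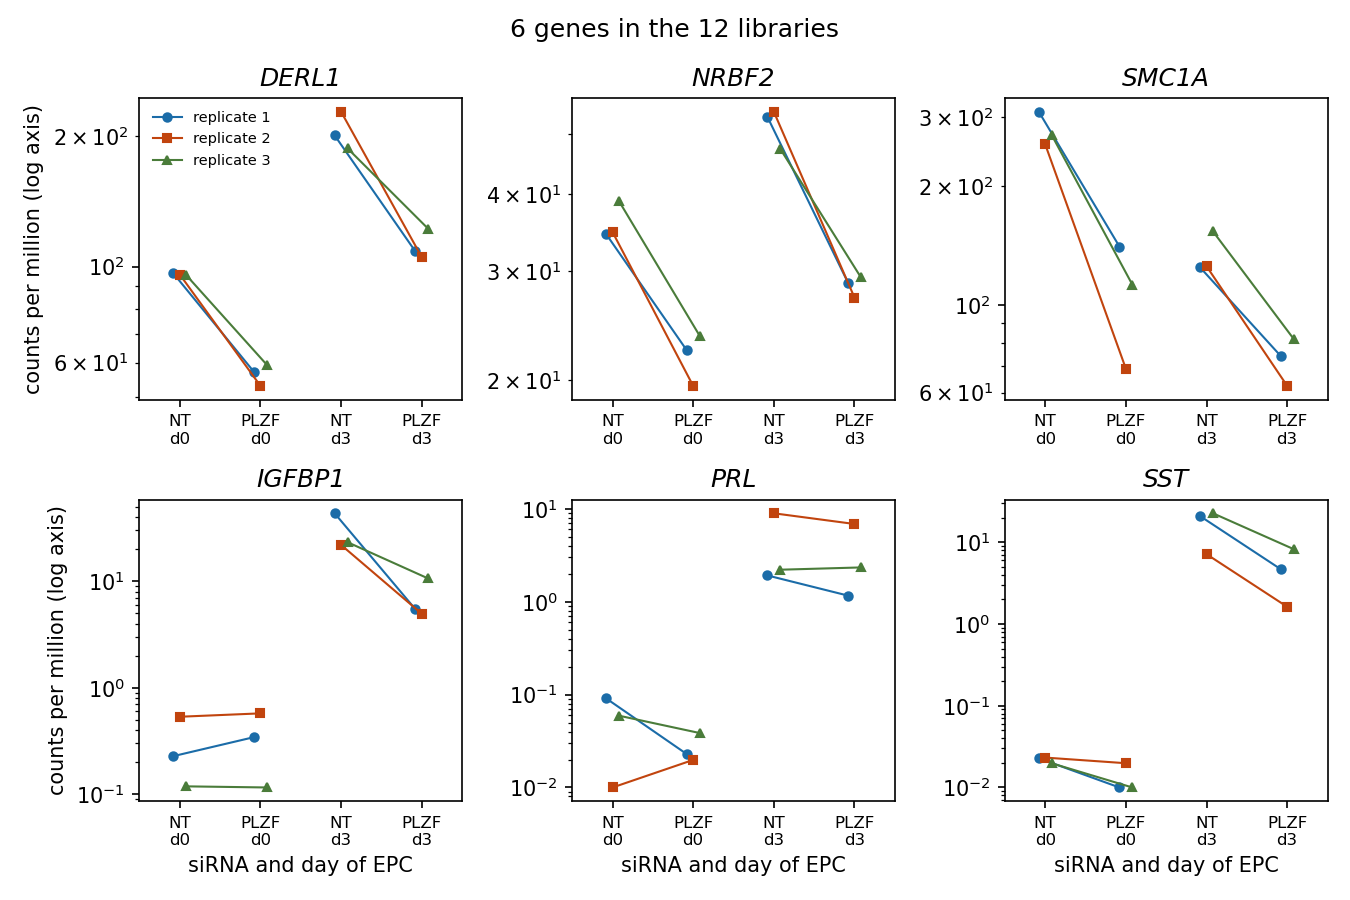
Level of DERL1, NRBF2, SMC1A, IGFBP1, PRL and SST in CPM (y axis, log scale) in each library by siRNA (NT, nontargeting) and day of EPC (d0, d3). Points are single libraries, lines join libraries of the same replicate number within a day, and values under 0.01 are drawn at 0.01. DERL1 and NRBF2 are lower with PLZF siRNA in all 3 pairs at both days.

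Several lists shifted as sets at day 3 by camera with a preset correlation, without member genes passing over all genes in edgeR. Ribosomal protein genes lay higher (adjusted p = 1.24e-10), with a median log2 fold change of 0.16, 0 of 29 called adjusted over the list alone and 25 with the block. Actin and contractile genes lay higher (adjusted p = 6.27e-05), and lists for the unfolded protein response (5.58e-05), cholesterol synthesis (7.57e-05), cAMP and CREB responsive genes (0.0172) and G2/M and mitosis (0.0294) lay lower. All 6 calls were lost with an estimated correlation, with an adjusted p of 0.307 for cAMP and CREB responsive genes, 0.534 for actin genes, 0.548 for ribosomal protein genes, 0.863 for G2/M and mitosis, and between 0.388 and 0.599 for the other 2 lists with and without the block. In the unfolded protein response list DNAJB9, a chaperone cofactor, was at -0.41 ± 0.10 and HSP90B1, an endoplasmic reticulum chaperone, at -0.45 ± 0.12, and 2 of 21 members fell adjusted over the list alone, with 7 by the block. DNAJB9 passed over all genes with the block (-0.40 ± 0.07). In the cholesterol list 3 of 22 members fell adjusted over the list alone with the block, and PCSK9, which lowers LDL receptor levels, fell over all genes (-0.84 ± 0.16 with the block). LDLR was at -0.35 ± 0.11 without the block. The decidual marker list did not pass (camera adjusted p = 0.198), with 0 of 33 members called over all genes or adjusted over the list alone in edgeR, and 3 lower over all genes and 4 adjusted over the list alone with the block. These 3 were SST, IL15, the interleukin 15 gene (-0.80 ± 0.13 with the block), and SCARA5, a ferritin receptor (-3.43 ± 0.31 with the block).

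Of the markers of other cell types, the leukocyte list had a median log2 fold change of -0.58 and a camera adjusted p of 0.0591. CD68, a lysosomal protein of macrophages, was at -0.58 ± 0.14 and was the 1 of 7 genes lower adjusted over the list alone, and with the block also over all genes (-0.59 ± 0.09 with the block). In edgeR 0 epithelial, endothelial or perivascular markers were called, with or without the block and adjusted over the list alone, and the camera adjusted p was 0.525, 0.701 and 0.701.

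In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were higher and 2 lower with PLZF siRNA at day 3, with 908 genes at an unadjusted p under 0.05. DESeq2 called 54 higher and 124 lower, and the replicate block in edgeR called 67 and 139. Fitted on the 6 day 3 libraries alone, edgeR called 0 and 0 without the block, so that DERL1 and NRBF2 were not called, and 714 and 894 with it. Leaving out any 1 of the 6 libraries or any replicate number left at most 1 gene without the block and, with it, 0 to 27 higher and 0 to 75 lower. The nontargeting day 3 library of replicate 3 was the one without which 1 lower gene was called.

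The fourth comparison followed EPC in cells that had received PLZF siRNA. PRL rose from 0.0271 to 3.46 ± 3.01 CPM (SD), IGFBP1 from 0.344 to 7.00 CPM (log2 fold change 4.34 ± 0.60, SE, n = 3 per group), FOXO1 by 2.30 ± 0.52, HAND2 by 2.35 ± 0.41 and WNT4 by 4.62 ± 0.62. BMP2 (0.0024 ± 0.40), PGR (1.43 ± 0.49) and EGR1 (-0.81 ± 0.64) did not pass without the block. Their adjusted p were 0.995, 0.0545 and 0.374 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the same test with the block PGR passed (1.53 ± 0.14, adjusted p = 6.68e-05). BMP2 (-0.06 ± 0.19, adjusted p = 0.821) and EGR1 (-0.67 ± 0.38, adjusted p = 0.178) did not. ZBTB16 had 949 counts at day 3 against 3 at day 0, a ratio of 385 with a 95% counting interval of 131 to 1870. CNR1 reached 50.3 ± 55.7 CPM (SD) from 5 counts over the group, IGF1 46.3 ± 53.3 CPM from 7 counts and P2RY14 5.41 ± 4.47 CPM from 5 counts. SST had 587 counts against 1, a ratio of 714 with an interval of 128 to 28261 (460 without the day 3 library of replicate 3). LEFTY2 had 205 against 2, a ratio of 125 with an interval of 34.1 to 1037 (51.7 without the day 3 library of replicate 2). SERPINB7 (-6.28 ± 0.53), MALL (-4.32 ± 0.33), RGS4 (-4.25 ± 0.40), SERPINB2, a serpin (-4.24 ± 0.99), KCNA3 (-4.21 ± 0.59) and MMP1, an interstitial collagenase (-3.86 ± 0.81), were among the strongest decreases.

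By list, 23 of 33 decidual markers rose and 1 fell, with 27 and 1 adjusted over the list alone (camera adjusted p = 5.26e-10, and adjusted p = 0.0339 with an estimated correlation). In the G1/S list 12 of 25 genes fell and 20 adjusted over the list alone, with MCM7 at -1.75 ± 0.48, and in the G2/M list 17 of 28 fell and 27 adjusted over the list alone, with the kinase gene PLK1 at -3.00 ± 0.83 (camera adjusted p = 1.30e-06 and 2.78e-08, and adjusted p = 0.468 with an estimated correlation for both). Cholesterol genes rose in 10 of 22 cases and 15 adjusted over the list alone, with LDLR at 1.36 ± 0.11 (camera adjusted p = 1.84e-06, and adjusted p = 0.319 with an estimated correlation). Of 25 progestin and glucocorticoid responsive genes 15 rose, and 17 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.05e-05, and adjusted p = 0.190 with an estimated correlation). Ribosomal protein genes rose in 17 of 29 cases and 23 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 1.30e-06, and adjusted p = 0.468 with an estimated correlation). Of 34 matrix genes 14 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 0.000499, and adjusted p = 0.514 with an estimated correlation), and 10 of 22 glycolysis genes fell, 12 adjusted over the list alone (camera adjusted p = 0.000862, and adjusted p = 0.319 with an estimated correlation). In the interferon list IFIT2 (-1.50 ± 0.23) and IRF7 (-0.88 ± 0.25) fell, 1 adjusted over the list alone and 11 of 22 with the block. Its camera adjusted p was 0.0509, and 0.00306 with the block, with adjusted p = 0.434 with the block and an estimated correlation. The endothelial list (camera adjusted p = 0.0509, and 0.0233 with the block) and the HOX list (0.0522, and 0.0219 with the block) also passed with the block only, with adjusted p = 0.370 and 0.334 with the block and an estimated correlation. Among epithelial markers KRT18 (-2.85 ± 0.27), KRT7 (-2.62 ± 0.72), KRT19 (-2.0 ± 0.32) and KRT8 (-1.32 ± 0.22) fell, the same 4 of 10 adjusted over the list alone (camera adjusted p = 0.109). Among perivascular markers MCAM (2.49 ± 0.40), CNN1 (1.96 ± 0.45), ACTA2 (1.52 ± 0.31) and STEAP4, with 0 counts at day 0, rose, the same 4 of 13 adjusted over the list alone (camera adjusted p = 0.0509). Among endothelial markers ROBO4 (-4.38 ± 0.69), ESAM (-4.05 ± 1.14), FLT1 (-1.87 ± 0.60) and ENG (-0.52 ± 0.13) fell, also 4 of 9 adjusted over the list alone. Of 7 leukocyte markers PTPRC fell, from 0.477 to 0.0247 CPM, with 0 called in edgeR adjusted over the list alone (camera adjusted p = 0.559). cAMP and CREB responsive genes, of which 9 of 21 rose and FOSB fell (-1.84 ± 0.41), the same 9 and 1 adjusted over the list alone, did not pass (0.0901). In all 2121 genes rose and 2137 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 949 and 708 by more than 2-fold. The replicate block called 3982 and 3881. Without all 4 libraries of a replicate number the counts were 806 and 706 (replicate 1), 902 and 768 (replicate 2) and 1128 and 1160 (replicate 3).

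Whether the siRNA changed the EPC response was tested by the interaction of siRNA and day. IGFBP1 had the most negative interaction among the 8 genes followed in every comparison, at -2.32 ± 0.86 on the log2 scale (SE, n = 3 per group), and BMP2 was at -1.09 ± 0.56, FOXO1 at -0.53 ± 0.73 and PRL at 0.49 ± 1.63. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes passed, with 445 at an unadjusted p under 0.05, and 0 with the replicate block, with 1666 at an unadjusted p under 0.05 and a smallest adjusted p of 0.281. DESeq2 called 1 gene without the block, and 91 higher and 115 lower with it. The different counts of called genes at day 0 and day 3 are therefore not shown to be a difference between the days for any single gene in edgeR.

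Calls were then compared between contrasts. Both genes that fell with PLZF siRNA at day 3, DERL1 and NRBF2, were among the genes that rose with EPC in nontargeting siRNA cells. With the replicate block 62 genes rose with EPC and were lower with PLZF siRNA at day 3, 20 fell with EPC and were higher, 29 were higher in both and 37 lower in both. Independent lists of the same lengths would share 41.3, 18.7, 19.9 and 38.9 genes. These contrasts share the nontargeting day 3 libraries with opposite signs. Across genes, which are not independent replicates, the log2 fold changes correlated at -0.116 (Pearson), with a covariance of -0.0449. In 20 simulations of unchanged groups the correlation was -0.521 to -0.482 and the covariance -0.0347 to -0.0304. The simulated groups held no difference between the days, so their correlation cannot be set against the observed one. The shared libraries could not be split with 3 per group, so part of the excess of 62 over 41.3 may come from them. Against the EPC effect averaged over both siRNAs, where the simulated correlation was -0.0208 to 0.0525, 60 genes were higher with EPC and lower with PLZF siRNA (48.2 for independent lists), 20 were lower and higher (22.2), 38 higher in both (23.2) and 42 lower in both (46.0). The Pearson correlation was -0.0278 and the Spearman correlation 0.0857.

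PLZF siRNA effects at day 0 and day 3 share no libraries. DERL1 and NRBF2 were lower at both days in edgeR without the block. With the block 87 genes were lower at both days and 29 higher at both, against 6.72 and 2.79 for independent lists, and 1 gene was higher at day 0 and lower at day 3. In fits with the block on the 6 libraries of each day, 496 genes were lower and 445 higher at both days (165 and 155 for independent lists), 50 were higher at day 0 and lower at day 3, and 13 the reverse. The log2 fold changes correlated across genes at 0.392, against -0.0308 to 0.0244 in the simulations, with a covariance of 0.0520 against -0.00198 to 0.00153. These ranges leave out variation that genes share between cultures.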

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

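DESeq2 with the replicate block, used in this part, was chosen after the data were seen. The effect of PLZF siRNA differed between day 3 and day 0 for 10 gene lists when the interaction of siRNA and day was tested with camera, although edgeR's quasi-likelihood test called 0 single genes for it (445 at an unadjusted p under 0.05, DESeq2 1 gene). G1/S and DNA replication genes were lowered less by PLZF siRNA at day 3 (median log2 fold change -0.33) than at day 0 (-0.93). The camera adjusted p was 8.43e-08, with a median difference of 0.60 on the log2 scale. In nontargeting siRNA cells these genes had themselves fallen by day 3 (median -2.18). G2/M and mitosis genes were at -0.79 and -0.87 (0.0482, median difference 0.10). Ribosomal protein genes (0.000167, median difference 0.12) and actin and contractile genes (0.0152, 0.14) had more positive log2 fold changes at day 3. The log2 fold change with PLZF siRNA was lower at day 3 for cAMP and CREB responsive genes (0.000167, median difference -0.45), the unfolded protein response (0.000169, -0.18) and cholesterol synthesis and uptake (0.000312, -0.24). It was also lower for decidual markers (0.00177), the type I interferon response (0.00306, -0.69) and extracellular matrix genes (0.0482, -0.18). With an estimated correlation only the cAMP and CREB list passed (adjusted p = 0.0388, and 0.0707 with the replicate block). For the others the adjusted p with an estimated correlation was 0.769 for G1/S, 0.792 for ribosomal protein, actin and interferon genes, 0.824 for G2/M and matrix genes, 0.648 for unfolded protein response and cholesterol genes and 0.443 for decidual markers. With the block and a preset correlation matrix remodelling enzymes passed too (adjusted p = 0.0460, against 0.0595 without it), and adjusted p = 0.712 with the block and an estimated correlation.

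In edgeR single members did not pass over all genes, while DESeq2 with the block called 91 genes higher and 115 lower for the interaction. With the block, 1 cAMP and CREB responsive gene, the coactivator gene PPARGC1A (-1.71 ± 0.38), and 2 unfolded protein response genes, DNAJB9 (-0.52 ± 0.10) and the transcription factor gene XBP1 (-0.38 ± 0.08), were lower adjusted over the list alone. In the cAMP and CREB list CREM, a cAMP-responsive transcription factor, had an interaction of -0.31 ± 0.13 (SE, n = 3 per group), NR4A3, an orphan nuclear receptor, -1.05 ± 0.36, and SIK1, a salt-inducible kinase, -0.81 ± 0.44. In the G1/S list MCM2 was at 0.97 ± 0.44, and in the decidual list IGFBP1 was at -2.32 ± 0.86 and negative in 3 of 3 pairs. In the unfolded protein response list DNAJB9 was at -0.53 ± 0.14. Groups of 3 libraries are too small for a test of single outlying values, and the deposited table held no data outside the comparisons.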

How the results depend on the processing

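The replicate block combined with DESeq2, with no low-count filter, with only the 6 libraries compared or with libraries left out, and the settings of the word search, were chosen after the data were seen. With the replicate block 4410 genes rose and 4149 fell from day 0 to day 3 of EPC with nontargeting siRNA, and 3982 and 3881 with PLZF siRNA. PLZF siRNA changed 618 and 717 at day 0 and 67 and 139 at day 3, and the interaction stayed at 0 in edgeR. With the block and RLE scaling these were 4304 and 4265, 4023 and 3885, 571 and 809, and 88 and 170. DESeq2 without the block called 219 and 363 genes at day 0, 54 and 124 at day 3 and 1 lower gene for the interaction. Without the low-count filter edgeR called 1 higher and 24 lower genes at day 0 and 1 lower at day 3, and with only the 6 libraries compared 0 and 0 at day 0 and 0 lower at day 3. With the block and only the 6 libraries compared, 3072 and 2631 genes were called at day 0, 714 and 894 at day 3 and 2703 higher for EPC with nontargeting siRNA. DESeq2 with the block called 1092 and 1360 genes at day 0, 483 and 536 at day 3, and 91 and 115 for the interaction.

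Among genes higher with EPC, 62 were lower with PLZF siRNA at day 3 with the block and 42 in DESeq2, against 2 in edgeR without the block. Lower with EPC and higher with PLZF siRNA were 20 and 13, higher in both 29 and 22, and lower in both 37 and 29. At both days 87 (block) and 77 (DESeq2) genes were lower and 29 and 18 higher with PLZF siRNA, and 1 gene was higher at day 0 and lower at day 3 with the block.

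Leaving out 1 library or 1 replicate number gave 1089 to 2621 higher and 1042 to 2728 lower genes for EPC with nontargeting siRNA, lowest without replicate 1 and highest without the nontargeting day 3 library of replicate 3. With PLZF siRNA EPC gave 806 to 1789 and 706 to 1829. PLZF siRNA gave 0 to 2 and 0 to 11 at day 0, where each of the 9 omissions moved the count and the highest came without the PLZF siRNA library of replicate 1, and 0 and 0 to 1 at day 3, where 1 gene was called only without the nontargeting day 3 library of replicate 3. The interaction stayed at 0. With the block the ranges were 2849 to 4139 and 3043 to 3935 for EPC with nontargeting siRNA, 2704 to 3428 and 2662 to 3500 with PLZF siRNA, 0 to 337 and 0 to 541 at day 0 (0 and 0 without each replicate number), 0 to 27 and 0 to 75 at day 3, and 0 to 1 and 0 for the interaction. The log2 difference in ZBTB16 at day 3 ran from -1.08 to -0.39. The overlaps of calls between contrasts without the block, at most 2, were 0 without each replicate number. With the block no gene was called at day 0 without any of the 3 numbers, or at day 3 without number 1 or 2, so the overlaps of those calls were 0 as well, and without number 3 edgeR called 3 higher and 4 lower genes at day 3.

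Of 569 results for named genes, the block moved 59 past the threshold and DESeq2 35. RLE scaling took 2 below it, no filter 18, the 6 libraries 37 and the omissions 525 of their values, and 12 rose past it. No call of a named gene changed direction in these settings, and 97 values that passed in neither fit changed sign. Of 120 list results, most of which had no call to lose, 32 lost the call with an estimated correlation. The only calls that stayed were those of decidual markers in both EPC comparisons and of cAMP and CREB responsive genes in the interaction. With the block 10 results gained a call, and without a filter 7. In the settings tried for the word search the z of CTCATTC ran from -14.9 to -13.6 at day 0 and from -14.4 to -12.7 at day 3.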

Other observations

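The tests of ZBTB16 for a swap, of loss of PLZF, of shared libraries and of other splits except at day 0 were chosen after the results were seen. The size of the EPC response differed between replicates. With nontargeting siRNA the log2 changes of replicates 1, 2 and 3 had slopes of 1.03, 1.01 and 0.669 on the mean of the other pairs, and with PLZF siRNA 0.95, 0.917 and 0.795. Genes over 2-fold numbered 3571, 3444 and 2733 with nontargeting siRNA and 2940, 2909 and 2699 with PLZF siRNA. Replicate 3 also had the lowest ZBTB16 with nontargeting siRNA at day 3, at 6.13 CPM against 14.6 and 19.0 CPM.

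Day 0 calls with PLZF siRNA arose while ZBTB16 had 0 to 3 counts per library with either siRNA. So little transcript to lose argues against loss of PLZF as the whole cause of the day 0 calls, with PLZF protein not measured. The spread of the effect over 11912 genes (average log2 CPM of at least 1) was 0.0411 at day 3 and 0.0779 at day 0. The difference was -0.0368, although ZBTB16 was higher at day 3. Over all 14834 genes the covariances between replicate pairs were 0.0443 to 0.0830 at day 3 and 0.0755 to 0.118 at day 0. These ranges overlap, with the day 3 value lower for each of the 3 combinations. The smaller spread at day 3 cannot decide on loss of PLZF. Those cells were also further from transfection, and the ZBTB16 difference there was within the spread between replicates. A microRNA-like action of the transfected siRNA may account for part of the decreases, since the 7-base word CTCATTC in 3′ untranslated regions went with lower values at a z of -13.6 at day 0 (permutation p = 0.001, the smallest the permutations can give) and -13.0 at day 3, rank 1 of 16371 words at both days and in each of 6 pairs, against 1.40 for EPC. In the fit with the replicate block 220 of 681 lower genes (32.3%) held it against 60 of 602 higher genes (9.97%) at day 0 and 1883 of 13398 genes (14.1%) in all, and at day 3 it was 74 of 135 (54.8%) against 8 of 64, and of the named genes it was in DERL1, NRBF2, SMC1A, RRP1B, FRMD8, ADAMTS4, HDHD1, MAP7, MAPK3, MTRR, SMARCD1 and TXNDC16 but not NOLC1, PM20D2, SST, RSPO3, FABP3 and SOCS3 among those that were lower, and in FOXO4 and TRPM4 among those that were higher; the siRNA sequence is not given, so whether this word belongs to a guide made against ZBTB16 cannot be told apart from a chance match, since 5 of 9 annotated ZBTB16 transcripts hold the word and 29.1% of all 7-base words occur in them. The exact word was absent from 461 lower and 542 higher day 0 calls, which were not searched for the shifted words TCATTCT (z -8.31) and TCATTCA (-7.73) or for GGCATCT (-8.00), all beyond the permuted extreme of -6.30 at day 0, and the 10 splits of the 6 libraries (1 as large, 52 genes in the real and 0 in the highest other) are too few for a share under 0.05.

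The day 0 effect of PLZF siRNA went with the EPC effect averaged over both siRNAs at a correlation of 0.257 across genes, with 359 genes higher and 421 lower in both with the block, against 214 and 238 for independent lists. Shared libraries alone gave -0.0239 to 0.0370 in 20 simulations with unchanged groups, in which genes varied independently of each other. Variation that genes share between cultures was not simulated, so the range does not exclude it as a source. The correlation was 0.283 over 11515 genes with no exact match to the word above, so exact matches alone do not account for it. It was 0.240 over the 14781 of 14834 genes outside the 2 cell cycle lists. The lists are too short for this to tell whether cell cycle genes at large account for it. Both effects had G1/S genes at negative medians, and no further explanation was tested. At day 3 the measures differed in sign, with a Pearson correlation of -0.0278 against -0.0208 to 0.0525 in the simulations, a Spearman correlation of 0.0857 against -0.0187 to 0.0301, and 38 genes higher in both against 23.2 for independent lists.

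ZBTB16 was not lower in 1 of the 3 libraries labelled PLZF siRNA at day 3. If the 2 labels of that pair had been swapped, genes that the siRNA moved at day 0 in the other pairs should move the opposite way in it. Of 200 such genes a share of 0.98 kept their day 0 direction there, against 0.82 and 0.855 in the other pairs and 0.56 at the 95th percentile of random lists, which argues against a swap. In that pair at day 3 the word above also kept rank 1, at a z of -8.82. A weak knockdown of a transcript that rose more in some cultures than in others was not tested and stays open.

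Other splits were counted for the remaining comparisons. For EPC with nontargeting siRNA (5184 genes in the real split), EPC with PLZF siRNA (4258) and PLZF siRNA at day 3 (2), 1 of 10 splits was as large, the highest other gave 0, and 10 splits are too few for a share under 0.05. The real split gave 8559, 7863 and 206 genes, and 1335 at day 0, with the replicate block, and the other splits that part the 3 pairs gave 0. Only 4 splits part the pairs, the real one included. The others reverse the real difference in some pairs and keep it in the rest. A real effect then adds to the spread, so these counts of 0 cannot decide on chance. For the interaction 40 of 40 splits gave as many genes as the real one, but with 0 genes in the real split of edgeR this outcome was fixed and decides nothing. At an unadjusted p under 0.05 there were 445 genes, and DESeq2 called 1 gene without the block and 91 higher and 115 lower with it.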
